A study of Mus musculus with 6 samples.

How the data were processed

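RNA sequencing data were available for 6 libraries of murine Kras/p53 mutant lung adenocarcinoma cells, 3 with a control guide (Brg1 WT) and 3 with a guide against Brg1 (Brg1 KO). The table of all genes deposited by the authors held expected counts for 22484 gene symbols. Per the submitters' processing notes, RSEM 1.2.12, Bowtie 1.0.1 and the mm9 genome were used, and neither their settings, the gene annotation nor the strandedness of the libraries was stated. The authors also deposited a normalized signal per library, which equalled the expected counts multiplied by a single factor per library, and how the factor was chosen was not stated. The deposited table further held the authors' fold change as a ratio, its log2 value and a false discovery rate (an adjusted p-value), each for Brg1 KO over Brg1 WT, and the authors' test was not named. The read counts of the sample key deposited by the authors gave 11570656, 44535875 and 22147451 total reads for Brg1 WT replicates 1, 2 and 3 and 14679350, 24332172 and 79943941 for Brg1 KO replicates 1, 2 and 3. Expected counts summed to 82.2% to 87.6% of these reads, and the highest total was 7.36 times the lowest. In the deposited table, 4600 genes were at 0 in all libraries, and 25 symbols had been turned into calendar dates, which held at most 0.235% of a library's counts and were left as they stood.

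The main test used the expected counts rounded to whole numbers, which moved no value by more than 0.5. Genes were kept by filterByExpr with a minimum count of 10, scaled by TMM and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjustment over 12559 genes and a threshold of 0.05. The biological coefficient of variation was 0.205. Smarca4 and Smarca2 were also compared by exact two-sided permutation tests. Gene lists (37, of which 32 had at least 5 tested members) were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists. None of 22 genes encoded by the mitochondrial genome was in the deposited table, so that list gave no result. Adjusted p-values of single genes come from edgeR and those of lists from camera unless another tool is named. Samples, comparison, tests, gene lists and naming rule were fixed before the data were examined.

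The genes named were Smarca4, Smarca2, Kras and Trp53, each SWI/SNF subunit past the threshold, and the 12 genes with the largest fitted change in each direction. The latter had at least 10 CPM in the higher group, groups that did not overlap, and a symbol that was not provisional. From each list, the 2 members with the smallest adjusted p in each direction were named. Further members were named from some lists, and these were chosen after their values were seen. A fold change against a group at 0 was computed against a floor of 3 counts over the group, 0.0457 CPM for Brg1 WT and 0.0296 CPM for Brg1 KO, and with 1 to 3 counts a ratio with a 95% exact binomial interval was given. Floors and intervals cover counting error only. Reads shared between near-identical genes could not be traced in the deposited values. Genomic positions were not given, because the reference at hand was GRCm38 and not mm9, and it served only to assign 12452 genes to chromosomes and neighbours by symbol.

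On simulated data with 200 changed genes among 12425 and the dispersions of these libraries, the test called 8.96% of genes changed 1.5-fold, 53.7% of those changed 2-fold and 97.0% of those changed 4-fold. Unchanged genes made up 9.40% of the calls there (11 genes). In the libraries themselves 38.7% of tested genes were called, and the adjusted threshold depends on the share of changed genes. These simulated rates therefore do not carry over to this comparison. Of 200 simulated lists with no shift, 1% had a camera p below 0.05. Genes were simulated independently of each other there. That share therefore does not cover lists with correlated members, and the estimates were 0.341 for DNA replication and 0.44 for G2/M.

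Replicates of a group were checked for identity, and none were copies of each other. Deviations from the group mean correlated across genes at 0.126, 0.273 and 0.316 between Brg1 WT and Brg1 KO libraries of the same number, and genes are not independent replicates. The numbers were therefore treated as a possible pairing, with the replicate number as a block in an alternative fit, although Brg1 WT replicate 1 correlated slightly more with Brg1 KO replicate 2 (0.138). Other alternatives were DESeq2 size factors, library totals, no low-count filter, a mean of at least 100 counts, the Wald test of DESeq2 1.42.0, limma-trend with a prior count of 2, adjusted p below 0.01, a change of at least 1.5-fold, and leaving out each library in turn. Fits without both libraries numbered 3 and the subtraction of chromosome medians were added after the data were seen. The normalized signal was not tested, and the deposited table with human symbols was not used, since it repeats the same fold changes.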

Results

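RNA was sequenced from murine lung adenocarcinoma cells derived from Kras/p53 mutant tumours (KP cells) and grown as adherent cultures. The cells had been edited with CRISPR/Cas9, either with a control guide named sgTomato (Brg1 WT, 3 libraries) or with a guide against Brg1 (Brg1 KO, 3 libraries). Brg1, encoded by Smarca4, is an ATPase of the SWI/SNF chromatin remodelling complex, and the comparison of the groups asked which transcripts differ when it is lost. Total expected counts were 9510178, 37863970 and 19326435 in Brg1 WT replicates 1, 2 and 3, and 12261861, 20202709 and 69998750 in Brg1 KO replicates 1, 2 and 3. Expression is given as CPM, counts per one-millionth of the TMM-scaled library total (mean ± SD, n = 3 per group), and log2 fold changes are Brg1 KO over Brg1 WT. The labels do not say whether replicates were separate cultures or clones, so p-values measure only the spread between these samples, which may be technical.

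Smarca4 mRNA was far lower in all 3 libraries labelled Brg1 KO than in the 3 labelled Brg1 WT. It measured 280, 305 and 229 CPM in Brg1 WT replicates 1, 2 and 3 and 33.9, 36.0 and 26.6 CPM in Brg1 KO replicates 1, 2 and 3. The mean fell from 271 ± 38.7 to 32.1 ± 4.90 CPM (n = 3), leaving 11.8% of the Brg1 WT level, with a log2 fold change of -3.08 (SE 0.18, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 3.08e-06). An exact two-sided permutation test of the log2 values gave p = 0.1, the smallest value that 3 against 3 libraries allow. Smarca2, the alternative ATPase of the complex, rose from 27.3 ± 3.70 to 55.7 ± 5.25 CPM (log2 fold change 1.03, SE 0.15, adjusted p = 0.000779).

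**Figure D1:**
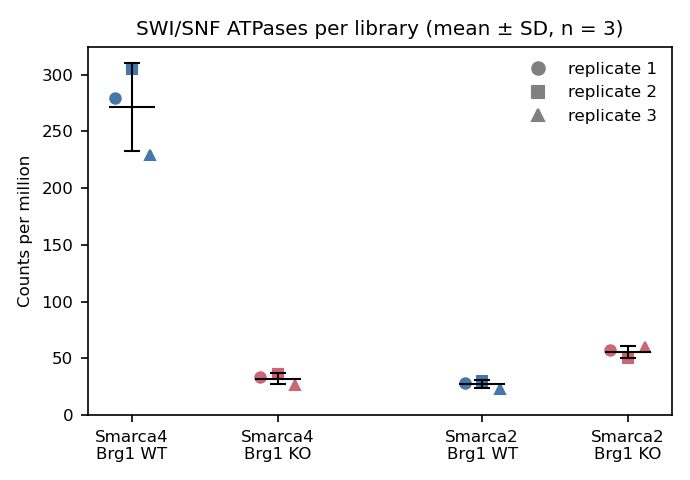
CPM (linear axis from 0) of Smarca4 and Smarca2 in the 3 Brg1 WT and 3 Brg1 KO libraries, with marker shapes for replicate numbers and the mean ± SD in black. Smarca4 lies between 229 and 305 CPM in Brg1 WT and between 26.6 and 36.0 CPM in Brg1 KO, while Smarca2 lies between 23.1 and 30.1 CPM in Brg1 WT and between 49.9 and 60.2 CPM in Brg1 KO.

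Among 25 tested SWI/SNF subunit genes, 6 rose, 3 fell and 16 did not pass the test, and the same 6 and 3 counts were obtained when adjusted over the list alone. Actl6a, an actin-related subunit, rose from 58.2 ± 7.96 to 97.8 ± 7.04 CPM, and Arid2, Bcl7c, Smarcd1 and Arid1a rose by 0.51, 0.51, 0.40 and 0.39 on the log2 scale. Pbrm1, a bromodomain subunit of the PBAF form, fell by 0.55 and the core subunit Smarcb1 fell by 0.43 on the log2 scale. With fewer libraries several of these calls ended while the folds stayed near those given. Arid1a missed the threshold without any 1 library other than Brg1 WT replicate 3 (adjusted p between 0.0669 and 0.139, log2 fold change 0.29 to 0.43), and so did Smarcd1 (0.0556 to 0.122, log2 fold change 0.34 to 0.45). Arid2 missed it without Brg1 WT replicate 1 (adjusted p = 0.0517) or Brg1 KO replicate 3 (0.0609), and Bcl7c without Brg1 WT replicate 1 or 2 or Brg1 KO replicate 2 or 3 (0.0504 to 0.115). Smarcb1 missed it without Brg1 WT replicate 2 or Brg1 KO replicate 1 or 2 (0.0794 to 0.12), and Pbrm1 without Brg1 KO replicate 2 (0.0793). With no low-count filter, Arid1a (adjusted p = 0.0834), Smarcb1 (0.0524) and Smarcd1 (0.0711) missed it, as did Smarcd1 without both libraries numbered 3 (0.0569). The count of subunits that rose accordingly went to 2 without Brg1 WT replicate 1 or Brg1 KO replicate 3 and to 3 without Brg1 WT replicate 2 or Brg1 KO replicate 2. The count that fell went to 1 without Brg1 KO replicate 2 and to 5 without Brg1 WT replicate 3.

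In Brg1 KO, the Wnt ligand genes Wnt6 and Wnt10a, the homeobox gene Hoxc6, the replication gene Mcm5 and the mitotic gene Top2a were higher. The keratin genes Krt7, Krt20 and Krt23, the nuclear receptor gene Hnf4a, Id2 and the fibronectin gene Fn1 were lower. Of 12559 genes tested, 4855 (38.7%) changed, 2272 higher and 2583 lower in Brg1 KO, and 4076 of the 4855 changed at least 1.5-fold. The counts of list members given below are to be read against these counts over all genes. By fitted fold change, 424 genes were at least 4-fold higher and 957 at least 4-fold lower, and 83 and 381 were at least 32-fold higher and lower. The floor of 3 counts was not applied to these counts of genes. Fitted folds of genes at 0 counts in a group can exceed what the floor allows, as for Hoxc5 (335.7 against at least 33.6). The groups parted along the first principal component of log2 CPM, which held 86.0% of the variance. Pearson correlations across genes, which are not independent replicates, were 0.968 to 0.985 within Brg1 WT, 0.986 to 0.989 within Brg1 KO and 0.82 to 0.841 between the groups. In the authors' deposited table, 5232 of the same 12559 genes had a false discovery rate below 0.05, and 4306 genes were called there and here, all 4306 in the same direction. Both come from the same libraries, so the shared direction is no independent support. Some genes named below as changed were not called there. Among them were Il33, Fosl2 (deposited false discovery rate 0.8545), Dhcr24 (0.6308), Areg (0.4856), Hif1a (0.4265) and Hist1h1c (0.3629).

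Of the gained genes, Wnt6 had 0 counts in Brg1 WT and 101 ± 25.9 CPM in Brg1 KO, at least 2200-fold higher against a floor of 3 counts over the group, and Wnt10a, another Wnt ligand, rose from 0.37 ± 0.399 to 129 ± 29.1 CPM (log2 fold change 8.63, SE 0.53, adjusted p = 4.32e-06). Sipa1l2, a GTPase-activating protein for Rap, was also at 0 counts in Brg1 WT and at 17.7 ± 1.61 CPM in Brg1 KO, at least 388-fold higher. Ces1g, a carboxylesterase, Scn3a, a voltage-gated sodium channel, Rbm20, a splicing regulator, and Adamts17, a secreted protease, had 1 to 3 counts in all of Brg1 WT, and their ratios were 1410 (95% counting interval 252 to 55600), 553 (153 to 4570), 297 (101 to 1440) and 233 (79.5 to 1130). Complement factor H (Cfh), ceruloplasmin (Cp), the ferritin receptor Scara5 and the immunoglobulin-domain receptor Ildr2 rose by log2 fold changes of 7.998, 7.41, 7.39 and 7.32. Cp was the most abundant of these, at 1.91 ± 0.782 CPM in Brg1 WT and 303 ± 142 CPM in Brg1 KO. Ifitm1, an interferon-inducible membrane protein with close paralogs whose reads may be shared, rose from 0.151 ± 0.176 to 61.7 ± 16.6 CPM. Brg1 WT replicate 2, the deepest of its group, set several of these sizes. Without it the bounds were 934 for Wnt6 and 165 for Sipa1l2, and the ratios 597 for Ces1g and 98.9 for Adamts17. Scn3a and Rbm20 then had 0 counts in Brg1 WT and were at least 207-fold and at least 142-fold higher. The log2 fold changes without it were 7.77 for Wnt10a, 9.68 for Ifitm1 and 11.84 for Scara5, and without Brg1 WT replicate 3 that of Wnt10a was 10.20. Without Brg1 WT replicate 1, Ces1g was at least 385-fold higher and the ratio of Adamts17 was 596, and without Brg1 KO replicate 3 the ratios of Scn3a and Adamts17 were 879 and 375.

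Of the lost genes, Apoc2, an apolipoprotein, fell from 56.3 ± 16.4 CPM and Pkp1, a desmosomal plakophilin, from 36.7 ± 32.2 CPM to 0 counts in Brg1 KO, at least 1910-fold and at least 1240-fold lower. Myo5b, a recycling endosome motor, Zfp532 and Zfp518b, zinc finger proteins, Nrxn1, a synaptic adhesion molecule, Dmd, which encodes dystrophin, and Prl2c4, a prolactin family member with near-identical copies, were likewise at 0 counts in Brg1 KO and at least 806, 536, 449, 469, 435 and 545-fold lower. Slc9a2, a sodium-proton exchanger, Tnnt2, cardiac troponin T, Smoc2, a matricellular protein, and Krt23, a keratin, had 1 to 3 counts in all of Brg1 KO against 94.2, 64.8, 136 and 84.5 CPM in Brg1 WT. Their ratios were 8860 (95% counting interval 1590 to 350000), 7110 (1280 to 281000), 4750 (1630 to 23000) and 4240 (1170 to 35000). With Brg1 WT replicate 3 left out, the bounds were 619 for Pkp1 and 247 for Prl2c4. Brg1 KO replicate 3, the deepest of its group, set the limits on all of these genes. Without it the bounds were 630 for Apoc2, 410 for Pkp1, 266 for Myo5b, 177 for Zfp532, 149 for Zfp518b, 155 for Nrxn1, 144 for Dmd and 180 for Prl2c4. Slc9a2, Tnnt2, Smoc2 and Krt23 then had 0 counts in Brg1 KO and were at least 1050-fold, 725-fold, 1520-fold and 945-fold lower. Tnnt2 and Pkp1 lie next to each other among the tested genes of their chromosome, as do Dmd and Tmem47, another lost gene.

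**Figure D2:**
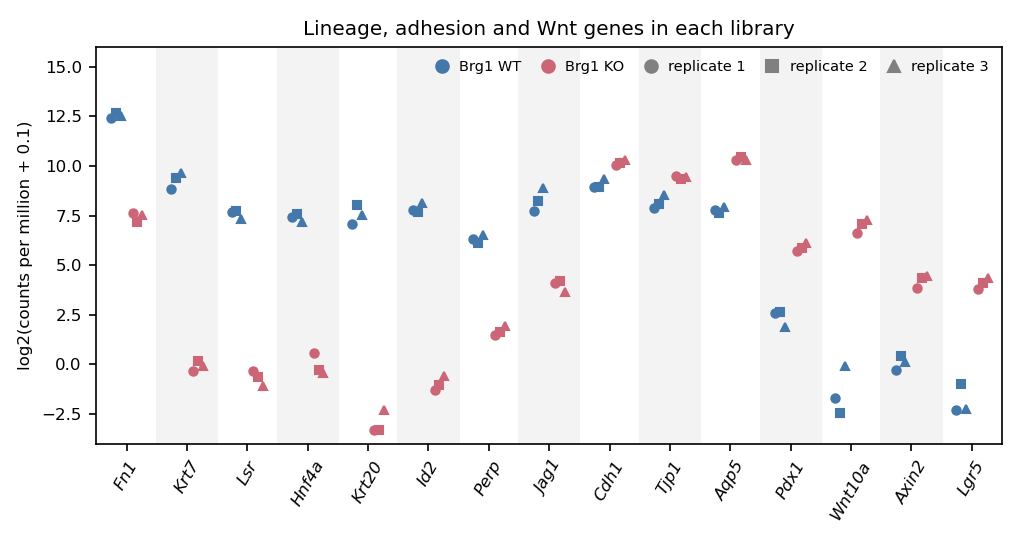
Expression of 15 genes in each of the 6 libraries, as log2(CPM + 0.1), with colour for group and marker shape for replicate number. Fn1, Krt7, Lsr, Hnf4a, Krt20, Id2, Perp and Jag1 are lower and Cdh1, Tjp1, Aqp5, Pdx1, Wnt10a, Axin2 and Lgr5 higher in each of the 3 Brg1 KO libraries than in any of the 3 Brg1 WT libraries.

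Proliferation genes rose together. Of 33 tested genes of G2/M and mitosis, 32 rose and none fell, also when adjusted over the list alone, with a list median log2 fold change of 1.13. Top2a, the mitotic topoisomerase, went from 349 ± 32.7 to 928 ± 62.6 CPM and Mad2l1, a spindle checkpoint protein, from 46.0 ± 2.85 to 132 ± 14.2 CPM. Cenpe was the member that did not pass the test. Of 47 DNA replication genes, 39 rose and none fell (40 and 0 adjusted over the list alone, median 0.96), among them the replicative helicase subunits Mcm5 (62.6 ± 7.09 to 214 ± 27.5 CPM) and Mcm3 (76.0 ± 9.38 to 246 ± 39.4 CPM). Genes of the ATR and Chk1 pathway and of replication fork protection followed, with 17 of 30 higher and none lower (18 and 1 adjusted over the list alone, median 0.65). Hltf, a fork remodeller, rose from 26.5 ± 6.19 to 88.4 ± 5.55 CPM and Timeless, a fork protection factor shared with the replication list, from 30.1 ± 1.398 to 71.1 ± 6.57 CPM. Among the members of that list, 1 was lower without Brg1 WT replicate 2 and 1 with the replicate number as a block. Camera, a competitive test of a list against all other genes, called these 3 lists higher (adjusted p = 1.61e-13, 1.61e-13 and 6.30e-06 in the order given). The calls were lost when the correlation between members was estimated, with adjusted p = 0.386, 0.393 and 0.301 with an estimated correlation.

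Other DNA repair genes went both ways, with 10 of 30 higher and 4 lower (12 and 4 adjusted over the list alone; camera adjusted p = 0.204). Mdc1, a DNA damage mediator, rose from 105 ± 0.862 to 229 ± 36.2 CPM and Rad51c, a recombination factor, rose by 1.31 on the log2 scale, while Xrcc5 (Ku80, end joining), Xpc (lesion recognition), Ercc1 (nucleotide excision) and Ogg1 (base excision) fell (log2 fold changes -1.26, -1.25, -0.96 and -0.62). The Ogg1 call ended without Brg1 WT replicate 1 or any 1 Brg1 KO library (adjusted p 0.0537 to 0.094). The p53 target list was also divided, with 6 higher and 6 lower of 22 under either adjustment (camera adjusted p = 0.789). Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21, rose from 14.8 ± 6.40 to 64.6 ± 18.8 CPM and Phlda3 from 7.62 ± 0.434 to 16.7 ± 1.68 CPM, whereas Perp, a desmosome-associated protein, fell from 80.3 ± 11.7 to 3.13 ± 0.519 CPM and Trp53inp1 from 54.5 ± 11.7 to 7.09 ± 0.774 CPM. Trp53 itself was 5.16 ± 0.916 CPM in Brg1 WT and 8.65 ± 0.898 CPM in Brg1 KO (log2 fold change 0.76, SE 0.22, adjusted p = 0.0239), a call that ended without Brg1 WT replicate 2 (adjusted p = 0.0678), Brg1 KO replicate 2 (0.0609) or Brg1 KO replicate 3 (0.095), or without both libraries numbered 3 (0.0704). Kras did not differ past the threshold (280 ± 70.9 and 241 ± 8.61 CPM, log2 fold change -0.22, SE 0.18, adjusted p = 0.369), and without Brg1 WT replicate 3 its log2 fold change was 0.025 (adjusted p = 0.882).

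**Figure D3:**
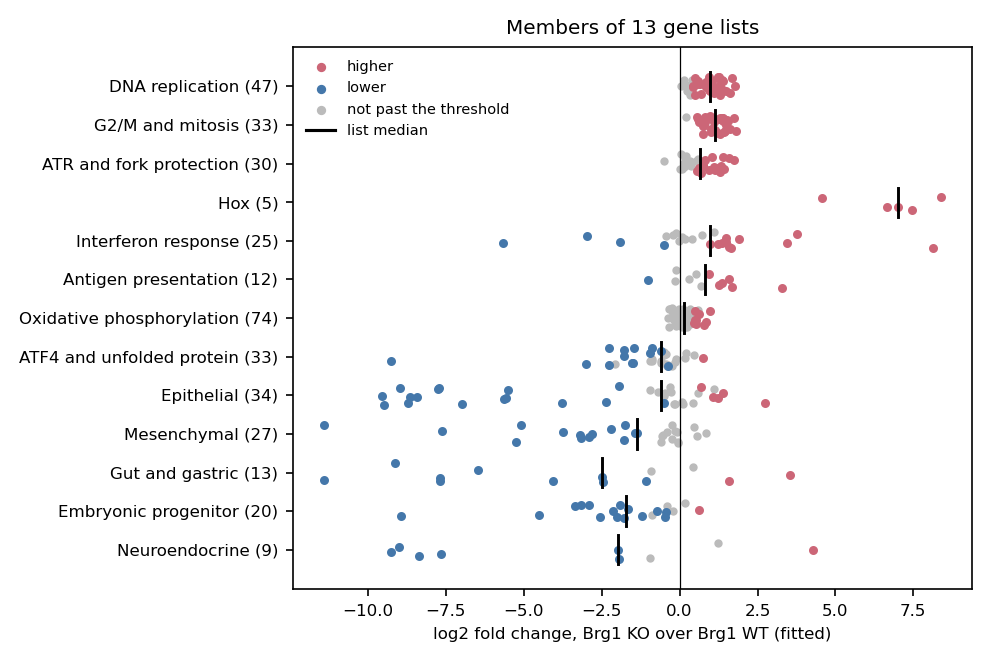
Fitted log2 fold changes (Brg1 KO over Brg1 WT) of the tested members of 13 gene lists, 1 point per gene, with the number tested in parentheses, colour for genes past the threshold and a bar at each list median. The DNA replication, G2/M and fork protection medians lie at 0.96, 1.13 and 0.65, and the gut and gastric, embryonic, mesenchymal and epithelial medians lie at -2.48, -1.73, -1.36 and -0.61.

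Of 13 tested gut and gastric lineage genes, 9 fell and 2 rose (10 and 3 adjusted over the list alone, median log2 fold change -2.48). Hnf4a, the hepatic and intestinal nuclear receptor, fell from 169 ± 22.7 to 0.919 ± 0.418 CPM and the intestinal keratin Krt20 from 195 ± 65.1 to 0.0344 ± 0.0595 CPM (log2 fold change -11.42, and -14.92 without Brg1 KO replicate 3). Pdx1, the pancreatic and duodenal homeobox factor, rose from 5.14 ± 1.41 to 60.1 ± 9.16 CPM and Cdx2, the intestinal homeobox factor, from 23.6 ± 4.74 to 69.6 ± 13.3 CPM. Without Brg1 WT replicate 3, 4 members were higher. Of 20 embryonic and progenitor genes, 15 fell and 1 rose (16 and 1 adjusted over the list alone, median -1.73). Id2, an inhibitor of basic helix-loop-helix factors, fell from 236 ± 41.5 to 0.424 ± 0.136 CPM and Mycl1, an L-Myc gene, from 6.51 ± 0.537 to 0.25 ± 0.0992 CPM. Lin28b, which blocks let-7 processing, rose by 0.62 on the log2 scale, a call that ended without Brg1 WT replicate 1 or 3 or Brg1 KO replicate 1 or 2 (adjusted p between 0.056 and 0.133), with library totals (0.0512) or with a mean of at least 100 counts (0.0506). Camera called both lists lower (adjusted p = 0.00209 and 3.63e-06). Neither call held, at adjusted p = 0.301 for each with an estimated correlation. Krt20, Id2 and Mycl1, at 7, 51 and 31 counts over all Brg1 KO libraries, were kept through their counts in Brg1 WT. They could only be lower in Brg1 KO, so both calls are partly fixed by the filter.

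Of 9 neuroendocrine genes, 6 fell and 1 rose (7 and 2 adjusted over the list alone, median -1.97). Insm1, a neuroendocrine transcription factor, fell from 21.7 ± 6.49 to 0.125 ± 0.0445 CPM and Ncam1, a neural adhesion molecule, from 102 ± 48.8 to 0.35 ± 0.166 CPM, while the synaptic vesicle protein Syp rose from 0.734 ± 0.0856 to 14.2 ± 2.03 CPM. With the replicate number as a block, 2 members were higher, as they were without Brg1 WT replicate 3 or without Brg1 KO replicate 3. Camera called the list lower (adjusted p = 0.0289, and adjusted p = 0.301 with an estimated correlation), but not without a filter on low counts (0.144) or with a mean of at least 100 counts (0.142). Insm1 and Ncam1, at 10 and 29 counts over all Brg1 KO libraries, were kept through their counts in Brg1 WT. They could only be lower in Brg1 KO, so this call is partly fixed by the filter. Of 34 Hox genes, 5 had enough counts to test. These 5 had 0 to 7 counts over all Brg1 WT libraries, so they were kept through their counts in Brg1 KO and could only be higher there. With no low-count filter, 10 of 22 were higher and 0 lower, with a median of 4.13 (camera adjusted p = 6.83e-05). Hoxc6 rose from 0.0969 ± 0.0391 to 14.1 ± 2.25 CPM, Hoxc4, Hoxb8 and Hoxa5 had ratios of 179 (95% counting interval 60.9 to 867), 125 (22.3 to 4980) and 26.2 (7.02 to 220), and Hoxc5, at 0 counts in Brg1 WT, was at least 33.6-fold higher. With Brg1 WT replicate 2 left out the bound for Hoxc5 was 14.2 and the ratio of Hoxb8 was 53.2, and without Brg1 WT replicate 3 Hoxb8 was at least 31.7-fold higher. Camera's adjusted p over the 5 was 0.000128, and 0.301 with an estimated correlation.

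Of 34 tested epithelial genes, 16 fell and 5 rose (17 and 5 adjusted over the list alone, median -0.61). Krt7, a simple epithelial keratin, fell from 645 ± 182 to 0.851 ± 0.158 CPM and Lsr, a tricellular junction receptor, from 192 ± 26.3 to 0.533 ± 0.166 CPM. Cdh1, which encodes E-cadherin, rose from 543 ± 94.3 to 1145 ± 94.5 CPM and the zonula occludens scaffold Tjp1 from 291 ± 68.1 to 681 ± 39.3 CPM, and Tjp2, Grhl2 and the integrin Itgb6, named after their values were seen, rose by 0.67, 1.39 and 2.73 on the log2 scale. Of the mesenchymal genes, 14 of 27 fell and none rose, also when adjusted over the list alone (median -1.36). The median was -0.52 without both libraries numbered 3, -0.60 with no low-count filter and -1.40 without Brg1 WT replicate 2. Fn1, which encodes fibronectin, fell from 5956 ± 565 to 177 ± 28.3 CPM and Fbn1, which encodes fibrillin, from 12.8 ± 2.07 to 0.0616 ± 0.0149 CPM. With the replicate number as a block 2 mesenchymal genes were higher, without Brg1 WT replicate 2 there were 3 and without Brg1 WT replicate 3 there was 1. Camera called the epithelial list (adjusted p = 0.00334) and the mesenchymal list (3.70e-05) lower, and each had adjusted p = 0.301 with an estimated correlation. Lsr and Fbn1, at 45 and 6 counts over all Brg1 KO libraries, were kept through their counts in Brg1 WT. They could only be lower in Brg1 KO, so these calls too are partly fixed by the filter.

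Collagen and matrix genes also went both ways, with 6 of 27 higher and 12 lower (7 and 13 adjusted over the list alone). Bgn, the proteoglycan biglycan, rose from 2.77 ± 1.15 to 113 ± 37.2 CPM and Vcan, the proteoglycan versican, from 59.6 ± 11.2 to 192 ± 30.6 CPM, while Col6a1 (collagen VI) fell from 32.9 ± 7.71 to 0.97 ± 0.296 CPM and Nid1 (nidogen) from 172 ± 64.8 to 9.97 ± 1.12 CPM. Camera did not call this list (adjusted p = 0.22), except without Brg1 WT replicate 1 (adjusted p = 0.0431). All 4 fibroblast markers with enough counts to test rose, too few for the list test. With any 1 library left out, 5 or 6 were tested, and camera called the list higher each time (adjusted p between 0.00205 and 0.0453). In those fits 4 or 5 markers were higher, and 1 was lower without Brg1 WT replicate 1 or any 1 Brg1 KO library. With no low-count filter 5 of 14 were higher and 1 lower (camera adjusted p = 0.0753). Gli1, a Hedgehog effector, rose from 0.0881 ± 0.0287 to 13.7 ± 3.42 CPM, Col1a1 from 2.64 ± 1.16 to 21.0 ± 6.83 CPM, and Pdgfra by 1.71 on the log2 scale. Col3a1 had a ratio of 15.7 (95% counting interval 5.18 to 78.1). Gli1 and Col3a1, at 6 and 3 counts over all Brg1 WT libraries, were kept through their counts in Brg1 KO. They could only be higher there, so the camera calls on this list are partly fixed by the filter. Other fibroblast markers were near 0 in Brg1 KO, with 3 counts of Col1a2, 2 of Dcn and 0 of Lum over all 3 libraries.

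Lung lineage genes moved apart as well. Among 13 alveolar type 1 genes, 2 rose and 7 fell (2 and 8 adjusted over the list alone; camera adjusted p = 0.244). Aqp5, a water channel, rose from 221 ± 24.8 to 1300 ± 69.6 CPM and Clic5 by 4.63 on the log2 scale, while Emp2 fell from 106 ± 20.2 to 1.36 ± 0.242 CPM and Cav1, which encodes caveolin, from 455 ± 189 to 97.9 ± 7.53 CPM. Among 11 alveolar type 2 genes 3 rose, Cebpa (14.6 ± 2.08 to 115 ± 33.9 CPM), Foxa2 (21.2 ± 6.35 to 51.7 ± 8.81 CPM) and Ctsh (1.10 on the log2 scale), and Foxa1 fell by 0.81, with the same counts adjusted over the list alone (camera adjusted p = 0.627). With the replicate number as a block 2 type 2 genes were lower, as they were without Brg1 WT replicate 2 or without Brg1 KO replicate 3. Nkx2-1, the lung lineage factor, was barely detected, with 12 counts over all Brg1 WT libraries and 16 over all Brg1 KO libraries, and Sftpc had 0 counts in either group. Among 7 airway genes, the aldehyde dehydrogenase Aldh3a1 (35.3 ± 6.51 to 290 ± 194 CPM) and Tppp3 (0.829 ± 0.19 to 3.98 ± 0.157 CPM) rose. The log2 fold change of Aldh3a1 was 3.04, and 2.33 without Brg1 KO replicate 3. Sox2, Aldh1a1, Hp and Cyp4b1 fell (log2 fold changes -2.54, -3.88, -1.92 and -1.46), with the same counts adjusted over the list alone (camera adjusted p = 0.627). The Hp call ended without Brg1 WT replicate 3 or Brg1 KO replicate 1 or 2 (adjusted p 0.0709 to 0.0842), and the Cyp4b1 call without Brg1 WT replicate 1 or 2 or Brg1 KO replicate 2 or 3 (0.0508 to 0.122). Without Brg1 WT replicate 3 the log2 fold change of Hp was -1.285.

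Among Wnt and Notch genes past the threshold, those of the Wnt pathway rose and those of the Notch pathway went both ways. In a joint list of 19 genes, 6 were higher and 5 lower under either adjustment (camera adjusted p = 0.38). The Wnt targets and feedback genes Rnf43 and Notum, and Dtx4 and Notch1 of the Notch pathway, rose by 3.40, 4.29, 2.34 and 1.90 on the log2 scale. Axin2, a feedback inhibitor of Wnt signalling, rose from 0.977 ± 0.247 to 18.7 ± 3.69 CPM and Lgr5, an R-spondin receptor, from 0.203 ± 0.168 to 17.1 ± 3.13 CPM (log2 fold change 6.04, and 7.26 without Brg1 WT replicate 2). The Notch ligands Jag1 (325 ± 131 to 15.9 ± 3.15 CPM) and Jag2 (55.9 ± 3.19 to 3.62 ± 1.00 CPM) fell, as did the Notch targets Hey1, Hes1 and Nrarp (log2 fold changes -3.52, -1.33 and -0.78).

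Interferon response genes were higher on balance. Of 25 tested, 12 rose and 4 fell, also when adjusted over the list alone (median 0.96). The median was 0.21 with no low-count filter, 0.29 without Brg1 KO replicate 3 and 1.23 without Brg1 WT replicate 2. Ifitm1 rose to 61.7 ± 16.6 CPM, and Ddx58, which encodes the RNA sensor RIG-I, rose from 5.36 ± 0.212 to 14.9 ± 1.26 CPM. The double-stranded RNA sensor gene Ifih1, Oasl1, Oasl2 and Trim25 fell (log2 fold changes -1.92, -5.67, -2.97 and -0.50), with the Trim25 call lost without Brg1 KO replicate 1 or 2 (adjusted p = 0.0815 and 0.117). Without Brg1 KO replicate 3 that of Oasl2 was -3.82, and without Brg1 WT replicate 2 that of Ifitm1 was 9.68 against 8.12. Of 12 antigen presentation genes, 6 rose and 1 fell, also when adjusted over the list alone (median 0.83). The peptide transporter gene Tap2 rose from 1.92 ± 0.766 to 18.6 ± 3.81 CPM and H2-T23, a class I gene whose reads relatives may share, from 50.2 ± 5.29 to 121 ± 22.6 CPM, while B2m, the class I light chain, fell from 157 ± 12.7 to 78.4 ± 4.65 CPM. Camera called both lists higher (adjusted p = 0.0292 and 0.0257). Neither call held, with adjusted p = 0.817 and 0.688 with an estimated correlation, and both ended without Brg1 WT replicate 3 (adjusted p = 0.0946 and 0.0503). The interferon call also ended without Brg1 WT replicate 1 (adjusted p = 0.0569), Brg1 KO replicate 1 (0.0577) or Brg1 KO replicate 3 (0.135), and with no low-count filter (0.104). Without both libraries numbered 3, neither the interferon list (0.101) nor the antigen presentation list (0.0705) was called.

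Brg1 WT replicate 3 stood apart from its group on the second principal component, which held 7.25% of the variance. Its log2 CPM exceeded the mean of the other Brg1 WT libraries by 1.67 for Chac1 and 1.68 for Trib3, genes of the integrated stress response. Brg1 KO replicate 3 lay below the rest of its group by -1.75 and -1.25. In the list of ATF4 and unfolded protein response genes, 13 of 33 fell and 1 rose (15 and 1 adjusted over the list alone, median -0.60). Gdf15, a stress-induced cytokine, measured 30.5, 24.5 and 121 CPM in Brg1 WT replicates 1, 2 and 3 and 0.12 ± 0.053 CPM in Brg1 KO (log2 fold change -9.25, -8.14 without Brg1 WT replicate 3 and -8.56 without Brg1 KO replicate 3). Atf5 fell from 170 ± 76.5 to 21.2 ± 3.08 CPM, and the endoplasmic reticulum chaperone gene Hsp90b1 rose from 459 ± 94.2 to 779 ± 68.4 CPM. Camera called the list lower (adjusted p = 0.00552; adjusted p = 0.85 with an estimated correlation), and without Brg1 WT replicate 3 the call ended (adjusted p = 0.0918) with 3 members higher. Of 74 oxidative phosphorylation genes 9 rose and none fell (6 and 0 adjusted over the list alone, median 0.13), led by the complex I subunit gene Ndufs8 (70.1 ± 2.73 to 125 ± 13.6 CPM) and the ATP synthase gene Atp5g1 (65.6 ± 7.004 to 128 ± 20.2 CPM). Among all 12559 tested genes 2272 rose, a larger share than 9 of 74. Camera called that list higher (adjusted p = 0.0359; adjusted p = 0.891 with an estimated correlation), but not without Brg1 WT replicate 3 (0.176, with 4 members lower), Brg1 KO replicate 2 (0.111) or Brg1 KO replicate 3 (0.0963). Nor was it called with DESeq2 (0.117) or without both libraries numbered 3 (0.342), where the ATF4 call also ended (0.18).

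The remaining signalling and metabolic lists were not called by camera. Of 26 NRF2 targets, 10 rose and 6 fell under either adjustment (camera adjusted p = 0.244). The glutathione synthesis gene Gclc (41.2 ± 3.42 to 92.7 ± 5.06 CPM) and Srxn1, a sulfiredoxin, rose, and Tkt, transketolase, and Osgin1 fell (log2 fold changes -1.04 and -2.63). Without Brg1 WT replicate 3 that of Osgin1 was -1.89. Without Brg1 KO replicate 2 the counts were 6 and 3, and without Brg1 KO replicate 3 they were 6 and 5. Of 25 NF-kB and cytokine genes, 5 rose and 7 fell (6 and 8 adjusted over the list alone; camera adjusted p = 0.705). The alarmin Il33 rose from 11.8 ± 10.1 to 997 ± 555 CPM, Birc3, Nfkb2, Lif and Cxcl3 rose by 2.29, 0.85, 1.46 and 2.66 on the log2 scale, and Tnfaip2 and the chemokine Cx3cl1 fell (log2 fold changes -5.21 and -2.02). Csf2, Ccl7, Cxcl16 and Ccl9 fell as well, and these calls ended without Brg1 KO replicate 1 or 2 (adjusted p 0.0509 to 0.0919). Their log2 fold changes in those fits were -3.74 to -1.40. The Csf2 call also ended with limma and without Brg1 WT replicate 3, where its log2 fold change was -1.15 (adjusted p = 0.0802). The Ccl9 call also ended without Brg1 WT replicate 2 (0.0619) or Brg1 KO replicate 3 (0.0583) and with limma (0.0659). The Cxcl3 call ended with DESeq2 (0.0576), with a mean of at least 100 counts (0.0501) and without any 1 library other than Brg1 WT replicate 3 (0.0522 to 0.146). Its log2 fold change was 1.93 without Brg1 KO replicate 3 and 2.99 without Brg1 KO replicate 1. The log2 fold change of Il33 was 6.39, and 7.35 without Brg1 WT replicate 3, and that of Tnfaip2 was -6.21 without Brg1 KO replicate 3. In the libraries numbered 3 of Brg1 WT and Brg1 KO, Cxcl5 was 3.39 and 3.56 and Nfkbia 1.86 and 1.77 higher on the log2 scale than in the rest of the group. With the replicate number as a block, 12 NF-kB genes were higher, and without Brg1 WT replicate 3 there were 15. Without Brg1 KO replicate 1 or without Brg1 KO replicate 2, 3 were lower.

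Of 24 MAPK output genes, 4 rose and 7 fell under either adjustment (camera adjusted p = 0.799). Spry1, a feedback inhibitor, rose from 0.987 ± 0.333 to 60.4 ± 8.57 CPM, Egr3, Ccnd1 and Egr2 rose by 1.06, 0.46 and 1.45 on the log2 scale, and the ligand Areg and the phosphatase Dusp4 fell (log2 fold changes -2.30 and -0.99). The Egr2 call ended without Brg1 WT replicate 1 or 2 or Brg1 KO replicate 3 (adjusted p 0.0595 to 0.0927). Dusp5, Spry2 and Epha4 fell as well, calls that ended without any 1 Brg1 KO library (0.059 to 0.156). Those of Spry2 and Epha4 also ended without Brg1 WT replicate 3 (0.052 and 0.0767) or both libraries numbered 3 (0.0566 and 0.0776). That of Epha4 ended without Brg1 WT replicate 1 too (0.0568). With Brg1 WT replicate 3 left out, the log2 fold change of Areg was -1.43. Without Brg1 KO replicate 1 or without Brg1 KO replicate 2, 3 were lower, and without Brg1 KO replicate 3, 4 were. Of 13 AP-1 genes 5 fell under either adjustment (camera adjusted p = 0.109), Junb, Fosb, Fosl2 and Maf with log2 fold changes of -0.94, -2.06, -0.84 and -1.34 and Mafb at least 55.2-fold. The log2 fold change of Fosb was -1.44 without Brg1 WT replicate 3, and the bound for Mafb was 18.3 without Brg1 KO replicate 3. Camera called the AP-1 list without Brg1 WT replicate 1 (adjusted p = 0.0405) or Brg1 WT replicate 2 (0.0253), and 3 members were lower without Brg1 KO replicate 2. The call for Fosl2 ended without Brg1 WT replicate 3 or Brg1 KO replicate 1 or 2 (adjusted p between 0.0549 and 0.127). The call for Maf ended without Brg1 WT replicate 1 or 2 or Brg1 KO replicate 2 or 3 (between 0.099 and 0.157), with library totals (0.0663) and with limma (0.0526). Of 26 YAP and TEAD targets, 5 rose and 6 fell under either adjustment (camera adjusted p = 0.799). Tissue factor (F3), Ankrd1, Dock5, Ptpn14 and Wwc1 rose by 2.86, 2.36, 1.19, 0.84 and 0.83 on the log2 scale, the kinase Axl fell by 1.42, and Nt5e had a ratio of 530 in favour of Brg1 WT (95% counting interval 94.5 to 21000). The Wwc1 call ended without Brg1 WT replicate 1 or 2 or Brg1 KO replicate 1 or 3 (adjusted p 0.0613 to 0.101). Ctgf, Amotl1 and Crim1 fell as well. The Ctgf call ended in the same fits as that of Wwc1 (0.0785 to 0.0992). The Crim1 call ended without Brg1 WT replicate 1 or 3 or Brg1 KO replicate 1 or 2 (0.0574 to 0.149). That of Amotl1 ended without any 1 library other than Brg1 WT replicate 1 (0.0515 to 0.196) and with no low-count filter (0.0651). With Brg1 KO replicate 3 left out, Nt5e had 0 counts in Brg1 KO and was at least 55.5-fold lower. With Brg1 WT replicate 3 left out, 11 YAP and TEAD targets were higher, and without Brg1 KO replicate 1, 3 were lower.

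Of 25 actin and adhesion genes, 9 rose and 4 fell (11 and 5 adjusted over the list alone; camera adjusted p = 0.244). The tropomyosin Tpm2 rose from 23.2 ± 3.33 to 102 ± 4.31 CPM and vinculin (Vcl) from 230 ± 53.4 to 608 ± 36.8 CPM, and Cald1, Flna, Tagln2 and Pdlim7 fell (log2 fold changes -2.10, -0.85, -0.74 and -0.44). The Tagln2 call ended without Brg1 KO replicate 1 or 2 (adjusted p = 0.0925 and 0.0983), and the Pdlim7 call without any 1 Brg1 KO library (0.0702 to 0.086) or both libraries numbered 3 (0.0629). Without Brg1 WT replicate 1, Brg1 KO replicate 2 or Brg1 KO replicate 3, 4 of them were higher, and without Brg1 KO replicate 1 or 2, 2 were lower. Of 35 glycolysis and hypoxia genes, 3 rose and 5 fell under either adjustment (camera adjusted p = 0.627). Egln3, a prolyl hydroxylase, rose from 34.8 ± 20.3 to 244 ± 48.8 CPM, Slc2a1 rose by 0.56, and Slc16a3, Hk2, Vegfa, Hk1 and Ddit4 fell (log2 fold changes -2.32, -1.14, -1.47, -0.58 and -0.96). The Slc2a1 call ended without Brg1 WT replicate 1, Brg1 KO replicate 2 or 3 or both libraries numbered 3 (adjusted p 0.0727 to 0.107), and the Ddit4 call without Brg1 WT replicate 2 or Brg1 KO replicate 1 or 3 (0.0539 to 0.0773). The log2 fold change of Egln3 was 2.80, and 3.42 without Brg1 WT replicate 2. Hif1a rose by 1.03, a call that ended without Brg1 WT replicate 1 or 2 or Brg1 KO replicate 3 (adjusted p 0.0621 to 0.0866). With the replicate number as a block 9 of these genes were higher. Without Brg1 WT replicate 2 and without Brg1 WT replicate 3 there were 9 and 6, and without Brg1 WT replicate 1 or Brg1 KO replicate 3 there was 1.

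Of 29 cholesterol and lipid genes, 3 rose and 2 fell (2 and 1 adjusted over the list alone; camera adjusted p = 0.627). Ebp, a sterol isomerase, rose from 63.0 ± 14.4 to 130 ± 18.0 CPM, Hsd17b7 and Sc5d rose by 1.28 and 0.60, and Pcsk9 and Dhcr24 fell (log2 fold changes -5.30 and -1.22). That of Pcsk9 was -4.58 without Brg1 WT replicate 2 and -6.22 without Brg1 KO replicate 3. Counts on this list moved with single libraries. With Brg1 WT replicate 2 left out, 12 members were higher and 1 lower and camera called it (adjusted p = 0.00103). Without Brg1 WT replicate 3, 4 were lower, without Brg1 KO replicate 1 or 2, 1 was lower, and without Brg1 KO replicate 3, 1 was higher and 1 lower. The block on replicate number gave 8 higher. Hsd17b7 missed the threshold without Brg1 KO replicate 3 (adjusted p = 0.0513). Sc5d missed it without any 1 library other than Brg1 WT replicate 2 or Brg1 KO replicate 1 (0.0503 to 0.119) and without both libraries numbered 3 (0.105), and Dhcr24 without Brg1 WT replicate 2 or any 1 Brg1 KO library (0.0527 to 0.104).

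Markers of other cell types gave no common direction. Of 2 immune markers with enough counts, Cd68 fell by 1.11 on the log2 scale, a call that ended without Brg1 WT replicate 1 or 2 or Brg1 KO replicate 2 or 3 (adjusted p 0.0523 to 0.126). Of 4 endothelial markers, Plvap rose by 3.36, and Flt1 and Eng fell (log2 fold changes -1.87 and -1.75). The counts for fibroblast (4 higher), immune and endothelial markers were the same when adjusted over the list alone. Of 50 ribosomal protein genes, whose pseudogenes may share reads, 9 fell, among them Rpl10 and Rpl15 (log2 fold changes -0.52 and -0.46), but none passed when adjusted over the list alone (camera adjusted p = 0.109). Without any 1 of the libraries other than Brg1 WT replicate 3, 1 or 2 ribosomal genes were lower, and 1 was higher without Brg1 WT replicate 3 and 1 with the block. The Rpl15 call ended without Brg1 WT replicate 1 or 2 or Brg1 KO replicate 1 or 2 (adjusted p 0.0572 to 0.0802). Of 10 histone genes, which are multicopy, Hist1h4i rose by 1.23 and Hist1h1c fell by 1.52 (0 and 1 adjusted over the list alone; camera adjusted p = 0.799). The Hist1h4i call ended without any 1 library other than Brg1 WT replicate 3 (adjusted p 0.0582 to 0.0863) and the Hist1h1c call without Brg1 KO replicate 1 (0.0539), while without Brg1 WT replicate 2, 2 histone genes were lower. The log2 fold change of Hist1h1c was -0.86 without Brg1 WT replicate 3. Of 16 immediate early and heat shock genes, Hsp90aa1 rose by 0.45 and Junb, Fosb and Zfp36 fell (log2 fold changes -0.94, -2.06 and -0.89), with the same counts adjusted over the list alone (camera adjusted p = 0.627). Hsp90aa1 missed the threshold without Brg1 WT replicate 1 or 2 or Brg1 KO replicate 1 or 3 (adjusted p 0.0504 to 0.095) and Zfp36 without Brg1 WT replicate 2 or Brg1 KO replicate 1 or 3 (0.0526 to 0.0585). With the block 2 of these genes were higher, and without Brg1 WT replicate 3 there were 2 higher and 5 lower, with Fosb at -1.44.

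Camera called 13 of 32 lists with at least 5 tested members, none with an estimated correlation (3 lists had an unadjusted p below 0.05), and fry's test of a common direction called 15. For the SWI/SNF, cholesterol and YAP lists the median was above 0 (0.03, 0.03 and 0.02) and the mean below 0 (-0.06, -0.10 and -0.12) with camera pointing up. Camera also pointed up for the histone list, with a median of 0.24 and a mean of -0.12, and for the alveolar type 2 list, with a median of -0.00322 and a mean of 0.34. Where edgeR called no member in a direction, members at an unadjusted p below 0.05 numbered 0 lower for DNA replication, G2/M and Hox, 0 higher for AP-1, 1 lower for fork protection, 1 higher for mesenchymal, 2 lower for oxidative phosphorylation and 2 higher for ribosomal genes. DESeq2 called 1 lower for fork protection, 2 lower for oxidative phosphorylation, 1 higher for ribosomal genes and 0 for the other 5, and limma called 0 for each.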

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

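The fits without both libraries numbered 3 were chosen after the result was seen. Smarca4 stayed lower in Brg1 KO past the threshold in every alternative (log2 fold change -3.18 to -2.96). Changed genes numbered 3795 to 5805 over single libraries left out, 4890 with library totals, 5367 with no low-count filter, 3916 with a mean of at least 100 counts, 5295 with DESeq2, 4894 with limma, 5400 with the replicate number as a block (4799 shared with the 4855) and 5344 without both libraries numbered 3 (4433 shared). At adjusted p below 0.01, 3244 genes changed, 1427 higher and 1817 lower. Of 150 named genes run in the alternatives, 128 kept direction and side of the threshold in every alternative that tested them, not all of which tested every gene, and 20 missed it in at least 1. Of 255 other called list members, some of them named, 76 missed it in at least 1 alternative. Of 888 list counts in the alternatives, 123 moved over 1.5 times. Kras had log2 fold changes of -0.315 to 0.025 over single libraries left out.

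With no low-count filter, camera gave adjusted p = 0.861 for alveolar type 2 (reversed), 0.104 for interferon and 0.144 for neuroendocrine, and a mean of at least 100 counts gave 0.142 for neuroendocrine and left 2 Hox, 3 airway and 4 histone genes, too few for the list test. With DESeq2 it gave 0.117 for oxidative phosphorylation and 0.641 for MAPK (reversed). Without both libraries numbered 3, 8 of the 13 lists were called and Hox, with 4 members left, was not tested, with p53 targets (0.82), glycolysis (0.987) and cholesterol (0.472) reversed, and oxidative phosphorylation (0.342), interferon (0.101), antigen presentation (0.0705) and ATF4 (0.18) not called. With an estimated correlation, 0 lists were called. Adjusted p was 0.393 for DNA replication, 0.386 for G2/M, 0.301 for fork protection, gut, embryonic, epithelial, mesenchymal, Hox and neuroendocrine, 0.891 for oxidative phosphorylation, 0.817 for interferon, 0.688 for antigen presentation, 0.85 for ATF4 and 0.891 for MAPK (reversed). With fry, SWI/SNF (0.63) and MAPK (0.865) reversed, alveolar type 1 (0.0422), airway (0.0314), collagen (0.0417) and immediate early (0.0385) passed, and oxidative phosphorylation (0.225) and ATF4 (0.112) did not. Over single libraries left out, camera adjusted p ran from 0.0129 to 0.0503 for antigen presentation, 0.0253 to 0.636 for AP-1, 0.000147 to 0.0918 for ATF4, 0.00103 to 0.961 for cholesterol, 0.0431 to 0.297 for collagen, 0.0518 to 0.973 for glycolysis, 0.698 to 0.932 for histone, 0.0133 to 0.135 for interferon, 0.584 to 0.959 for MAPK, 0.0775 to 0.909 for NF-kB, 0.00372 to 0.176 for oxidative phosphorylation and 0.264 to 0.974 for YAP. Among these, camera's direction reversed for glycolysis and YAP without Brg1 WT replicate 1, cholesterol without Brg1 WT replicate 1 or 3, MAPK without Brg1 WT replicate 3 or Brg1 KO replicate 1, histone without Brg1 WT replicate 2 or Brg1 KO replicate 2, and NF-kB without Brg1 KO replicate 3 (0.472). The cause was not tested for any of these. A different pseudocount was not run, since counts were available. With 3 libraries per group, a gene that missed the threshold is not shown to be unchanged.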

Other observations

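The chromosome rotation test, the fibroblast test, the test on the share of epithelial cells, the chromosome SDs of libraries 1 and 2, the fits without both libraries numbered 3 and the subtraction of chromosome medians were chosen after the result was seen. The libraries numbered 3 differed from the rest of their group in the same direction in Brg1 WT and Brg1 KO for several genes. The nuclear RNA Malat1 was lower by -2.08 and -2.10 on the log2 scale, while the chemokine Cxcl5 (3.39 and 3.56), the NF-kB inhibitor Nfkbia (1.86 and 1.77) and Cebpb (1.58 and 1.57) were higher. Xist, the RNA of the inactive X chromosome, measured 637 ± 250 CPM in Brg1 WT and 1181 ± 567 CPM in Brg1 KO (adjusted p = 0.105). It passed the threshold with the replicate number as a block (0.00115), with no low-count filter (0.04), with DESeq2 (0.0433), without both libraries numbered 3 (0.00209) and without Brg1 KO replicate 3 (0.0294). The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had at most 5 counts in either group. The most abundant transcript in Brg1 WT, A130040M12Rik, fell from 20070 ± 2572 to 8330 ± 421 CPM.

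Genes on the same chromosome shifted together between Brg1 KO and Brg1 WT. The SD over 20 chromosomes of the median log2 fold change was 0.17, against at most 0.161 in 1000 rotations of the fold changes along the gene order (permutation p = 0.001, the smallest they can give). The highest median was 0.39 (95% bootstrap interval 0.35 to 0.45, 464 genes, on the chromosome of Pten and Fen1) and the lowest -0.30 (-0.37 to -0.24, 411 genes, on that of Rb1 and Gata4). Each library against the other 2 of its group gave an SD of 0.0382, 0.0349 and 0.0589 for Brg1 WT replicates 1, 2 and 3 and 0.0229, 0.0238 and 0.0219 for Brg1 KO replicates 1, 2 and 3, which argues against differences of this kind as the source, while a copy-number or other chromosome-wide difference between the lines may contribute and stays open. Of 66 genes with at most 3 counts in Brg1 KO and at least 5 CPM in Brg1 WT, 20 were at 0 counts in all Brg1 KO libraries. Of the 66, 12 lay next to another such gene, against at most 6 in shuffles of the gene order. They were Steap3 and En1, Tnnt2 and Pkp1, Rorc and Tdrkh, Pilrb1 and Pilrb2, Cxx1b and Ddx26b, and Tmem47 and Dmd. Shuffles also break up any shared expression of neighbours. The SD over chromosomes was at most 0.0476 in shuffles, against at most 0.161 in rotations. The count of 12 therefore cannot tell deletions in the Brg1 KO line from other sources of shared loss, and deletions stay open for some lost genes.

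DNA replication and mitotic genes were higher in Brg1 KO under each scaling, with list medians of at least 0.957. After subtraction of the chromosome medians the median of the 80 genes was 1.06 (95% bootstrap interval 0.97 to 1.16), against 1.04 before. Without both libraries numbered 3, the lower of the list medians was 0.903. Chromosome medians ran only from -0.30 to 0.39, too small to account for a median of 1.04, so their subtraction could not have removed it. The scalings moved the median of all genes only between -0.023 and 0.024. They could hardly lower the list medians and so do not decide on scaling as a source. The value without both libraries numbered 3 argues against these libraries as the whole source. The loss of Brg1, which the design names, stays among the open explanations, untested apart from other differences between the lines.

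Of 34 epithelial genes, 16, among them Krt7 and Lsr, were lower in Brg1 KO (camera adjusted p = 0.00334; adjusted p = 0.301 with an estimated correlation), while Col1a1 and Col3a1 were higher. Fibroblasts in the cultures are unlikely to account for this, because the median of Col1a2, Dcn and Lum was 0.111% of the level of Col1a1. A lower share of epithelial cells would not by itself raise the 5 epithelial genes that rose (Cdh1, Tjp1, Tjp2, Grhl2 and Itgb6). That rule was set after these rises were known, so it cannot decide whether the lines differ in their mix of cells. A change within the cells stays open as a hypothesis found and tested on the same data.

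Of the 10 splits of the 6 libraries into 3 and 3, only 1, the real one, called 4855 genes, and the highest other count was 0. Every other split mixes both groups in each arm, so the difference between the groups widens the spread within the arms. Their gene counts therefore had to be low and cannot decide whether the real count arose by chance. For gene lists, 4 of the 10 splits called as many as the real 13, and the highest other count was 17. The other 3 splits that part each replicate pair called 0 genes and 11 to 15 lists. Splits of 6 libraries are too few for a share below 0.05.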
